A study of Saccharomyces cerevisiae with 328 samples.

How the data were processed

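PolyA RNA of 328 single deletion strains of Saccharomyces cerevisiae was sequenced on an Illumina HiSeq instrument, 1 library per strain. Per the labels, cells grown overnight were diluted and allowed to divide 2 to 3 times, and RNA was extracted in 96 well plates. The deposited tables hold, per the series design, log2 ratios of each deletion strain to the wild type strain, 255 strains in the first and 73 in the second. The base of the logarithm is not written: it was taken as log2 because whole-chromosome shifts reach 0.95, above the 0.693 and 0.301 that a doubling gives in natural and decimal logarithms. Bowtie is the only tool the submitters name; its version, the genome build, the counting and the normalization for depth are not given in the sources used here. The depth per library is therefore unknown, and no interval or limit that needs it is given.

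The first table has 6701 rows and the second 6698, without a gene column. The second was matched to the first by position: with no offset the gene means of both correlated at 0.979, and no offset gave the best match in 67 of 67 windows of 100 rows, while the offsets of up to 5 rows in either direction gave at most 0.0463. The 3 further rows are empty. A total of 4922 genes had any value; 51 unnamed rows had none. Empty cells were kept as missing (median 30.1% of a strain, 27.7% to 46.9%). Values ran from -5.32 to 7.83, and strain medians from -0.45 to 0.31 with a median of -0.13. Genes with a value in at least 80% of strains were tested, 4499 in all, of which 4422 matched the reference annotation of the R64 genome that gave coordinates; 2142 had a value in every strain. No pseudocount was added, since the values are already ratios.

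Groups followed the function of the deleted gene and were fixed, with the gene lists, the pairs of regulator and list, the tests, the rule for named genes and a first set of other settings, before the data were examined. Each class was compared with the 227 other deletions in 1 limma fit over all groups (limma 3.58.1, R 4.3.3; lmFit and eBayes), with Benjamini-Hochberg adjustment over genes and a threshold of 0.05; small and large subunit deletions were also compared with each other. The lists were ribosomal protein genes of the small (56) and large (81) subunit, ribosome biogenesis (106), translation factor (26), amino acid biosynthesis (62), sulfur and methionine (23), stress-induced (55), respiration and TCA cycle (45), glycolysis (17), proteasome (32), DNA damage (8), phosphate (11), unfolded protein response (7), ergosterol (15), iron regulon (12), nitrogen catabolite (10), cell wall integrity (9), a-cell (6), alpha-cell (4) and haploid genes (7). They were tested with camera (preset correlation 0.01, and an estimated one) and fry, and by permuting class labels over the strains' list means (100000 permutations, two-sided), adjusted over 190 tests. Correlations between 8 list means across strains used 100000 permutations. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and scikit-learn 1.9.0 were used.

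Named genes were those past the threshold, without genes deleted in the class and those within 5 open reading frames of one: the 12 largest rises and falls for the ribosomal classes, the 4 largest for the others and for the contrast of both ribosomal classes, and up to 4 called members per list. Genes given only with the batch as a term were taken by the same rule. Single strains have the deleted gene and the first 3 members of their list.

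Library batches were found by a Gaussian mixture on 4 principal components (10 starts). They were entered as a term of the fit, as strata of the permutations, and subtracted in the correlations. All uses of batches, the fits without strains whose deleted gene was not lowered, the first table alone and leaving out each strain of a class were chosen after seeing the data, as was 5 in place of 4 batches. The settings fixed beforehand were centring each strain on its median, only genes with a value in every strain, another reference, moderated variances with a trend, and leaving out strains with a chromosome shifted by over 0.4. For lists they were medians in place of means and no deleted genes. A pseudocount, a filter on level and lists matched on level were not run, since no levels are given.

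The fit was tested on the values of the other deletions, with a random set of them taken as a class. Of 4499 genes, 100 were shifted by 0.5 and 100 by 1 in that set. With 18 strains it found 89% of changes of 0.5 and 100% of changes of 1, with 14 strains 84% and 100%, and with 6 strains 42% and 95%. False calls were 19, 27 and 17 (9.14%, 12.8% and 11.0% of all calls) without the batch as a term and 6, 1 and 2 (3.06%, 0.538% and 1.40%) with it. In these draws the pooled fit exceeded the 5% set. Each size and model had 1 draw of strains, and real differences between strains count as false calls, so no rate follows for either model. With shuffled class labels 4.74% of 190 list tests had p under 0.05. Growth rate, in the series title, was not analysed here. All tests are two-sided unless stated.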

Results

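The series holds polyA RNA profiles of 328 strains of budding yeast, Saccharomyces cerevisiae, each lacking 1 gene, given as log2 ratios to the wild type strain. Cells were in exponential growth, and each strain has 1 library. The series title asks how the expression of protein synthesis and amino acid biosynthesis genes is connected to growth rate; growth rate was not analysed here. By the function of the deleted gene, 18 strains lacked a protein of the small ribosomal subunit and 14 a protein of the large subunit. A further 7 lacked a ribosome biogenesis factor, 6 a member of the Elongator or URM1 pathways (which modify transfer RNA), 6 a subunit of Mediator (the bridge between activators and RNA polymerase II), and 8 a recombination repair factor. The remaining classes were 13 strains without a vacuolar or endosomal sorting factor, 17 without a chromatin factor, 12 without a mitochondrial function, and all remaining strains, called other deletions, served as the reference. The strains of a class are its replicates, and the limma fit takes 1 spread per gene over the strains of all groups, most of them other deletions. Where a class varied more than that, as for RPS22B and YGL088W below, the SE and p-value understate the spread within the class. The depth of the libraries is unknown.

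Deleting a gene should empty its own mRNA. Most libraries checked had it lowered past a lenient threshold of -0.5 or empty, but only a minority had it empty or the lowest of all strains. Of 258 strains whose deleted gene had a value in at least 80% of strains, all but 60 had it empty or below -0.5 relative to the median of their library batch. Among libraries in which the deleted gene kept a value, it was the lowest of all strains in 70 (33.5%) and under -1 in 63.2%. It was empty in 49 of the 258, which is 18.99% against a mean of 1.60% of cells for the same genes elsewhere. The median of the deleted genes that kept a value was -1.33. Among the ribosomal protein deletions, the libraries labelled RPS1A, RPS16A, RPS10B, RPS19B, RPL19B and RPL16B did not show a lowered deleted gene.

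By a mixture model on the values themselves, the libraries fell into 4 groups that the labels do not name, holding 80, 73, 96 and 79 strains. They are called batches here, but whether they are technical or biological is not known. These batches took 29.1% of the variance. A mixture of 5 had a lower Bayesian information criterion (7457 against 7553), and with 5 batches as a term the count for small against large subunit deletions was 25 in place of 49. Small subunit deletions were spread over them as 2, 3, 9 and 4 strains, and large subunit deletions as 1, 4, 6 and 3. A median of 468.5 genes per strain lay at least 2-fold from wild type (246 to 1333), against 68.5 (1 to 1137) relative to the batch mean. Subtracting the batch mean also removes the difference from wild type that strains share, so this drop does not measure the batches. The median strain SD was 0.437 around each gene's mean over all strains and 0.366 around its batch mean. Because of the variance the batches took, values with the batch accounted for are given beside many of the pooled ones.

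**Figure D1:**
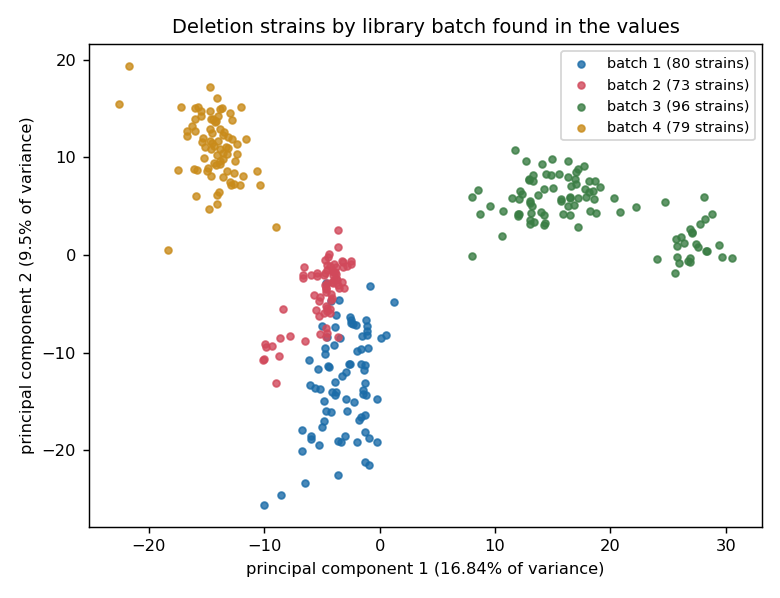
Each point is 1 deletion strain, placed by its scores on the first and second principal components of the log2 ratios (16.84% and 9.5% of the variance) and coloured by the library batch found in the values. The batches of 80, 73, 96 and 79 strains occupy different regions.

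Strains without a small subunit protein had lower mRNA of some heat shock, glycolytic and secretory chaperone genes than the other deletions, and higher mRNA of several large subunit proteins. HSP104 (YLL026W, chromosome XII, 88623 to 91349), the disaggregase, fell by 0.52 ± 0.10 (SE, n = 18 against the other deletions; limma adjusted p = 0.000182; lower in 17 of 18 strains). Its mitochondrial relative HSP78 (YDR258C, chromosome IV, 971808 to 974243) fell by 0.71 ± 0.11 (limma adjusted p = 3.15e-06; 17 of 18). KAR2, the chaperone of the endoplasmic reticulum, fell by 0.38 ± 0.09 (limma adjusted p = 0.00512), and PDI1, its disulfide isomerase, by 0.30 ± 0.06 (limma adjusted p = 0.000441). RPL25 (YOL127W, chromosome XV, 80348 to 81190), encoding a large subunit protein, rose by 0.31 ± 0.06 (limma adjusted p = 0.000442; higher in 16 of 18). With the library batch as a term HSP104, HSP78, KAR2 and PDI1 fell by 0.52, 0.67, 0.31 and 0.25 and RPL25 rose by 0.25, each with limma adjusted p of at most 0.00711.

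In all, 69 of 4499 genes passed limma at an adjusted p of 0.05, 14 higher and 55 lower. With the library batch as a term 3.45% of the genes tested passed in place of 1.53%, 43 genes (0.956%) higher and 2.49% lower, and 59 genes were called in both fits. The balance of rises and falls depended on centring: with each strain centred on its median 17 genes were higher and 24 lower, and with batch and centring together 79 were higher and 42 lower. Of the 69, 4 were genes deleted in the class or neighbours of one, among them RPS9B and RPS16A.

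Small subunit ribosomal protein genes were called in both directions. Of 56 tested, 3 rose and 3 fell, and 9 rose and 5 fell when adjusted over the list alone. With the batch as a term rises outnumbered falls, with 9 and 3 over all genes, 24 and 5 over the list alone, and 47 of 56 differences positive. Many have near-identical copies, so the assignment of reads between copies is uncertain. RPS22B (YLR367W, chromosome XII, 856442 to 857317) fell by 0.86 ± 0.08 (limma adjusted p = 2.2e-19), from 0.33 ± 0.29 (SD) in the reference to -0.53 ± 0.69 in the class, and was lower in 16 of 18 strains. RPS9A fell by 0.65 ± 0.12 (limma adjusted p = 5.88e-05; 16 of 18), although it stood at 3.12 in the strain without its copy RPS9B. RPS24B rose by 0.32 ± 0.08 (limma adjusted p = 0.0106) and RPS4A by 0.19 ± 0.05 (0.0244). One library of the class, RPS24A, had a raised chromosome IX, which carries RPS24B.

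Of 81 large subunit genes, 4 rose and 0 fell over all genes, and 16 rose and 0 fell when adjusted over the list alone; 61 had a positive difference. Besides RPL25 these were RPL43B (0.25 ± 0.05), RPL14A (0.21 ± 0.05) and RPL1A (0.18 ± 0.05). With the batch as a term 24 rose and 0 fell, RPL36A by 0.31 and RPL27B by 0.28. The mean of the list was 0.04 ± 0.12 (SD) in the class and -0.06 ± 0.13 in the reference. That difference of 0.09 did not pass (permutation adjusted p = 0.0849), whereas with labels permuted within batches it was 0.13 (adjusted p = 0.00095). Within the 4 batches it was 0.16, 0.17, 0.12 and 0.12.

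Amino acid biosynthesis genes were called mostly downward: 0 of 60 rose and 3 fell, and 2 rose and 12 fell when adjusted over the list alone, against 0 and 4 and, over the list alone, 0 and 6 with the batch as a term. HIS4, a histidine enzyme, fell by 0.57 ± 0.15 (limma adjusted p = 0.0189; 16 of 18 strains). ASN2 (asparagine synthetase) fell by 0.22 ± 0.06 and ARO3 (the aromatic pathway) by 0.35 ± 0.10; with the batch as a term ARO3 stood at -0.23 with limma adjusted p = 0.128. The list mean differed by -0.12, which did not pass (permutation adjusted p = 0.200; -0.10 and 0.161 within batches). GCV2, a subunit of the glycine cleavage system outside the list, rose by 0.43 ± 0.12 (limma adjusted p = 0.0292).

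All of the 7 unfolded protein response genes had negative differences; 2 fell, and 4 fell when adjusted over the list alone. Their mean was -0.53 ± 0.23 (SD) against -0.26 ± 0.30, a difference of -0.27 (permutation adjusted p = 0.0247; lower in 17 of 18 strains), and -0.29, -0.25, -0.18 and -0.08 in the 4 batches. Centring each strain on its median ended this call (-0.20, adjusted p = 0.0990). Stress-induced genes had 0 rising and 2 falling of 45, HSP78 and HSP104, and 4 falling when adjusted over the list alone. Their mean difference was -0.25 (permutation adjusted p = 0.222) and -0.32 within batches (0.0205). The cytosolic chaperone SSA1 also fell, by 0.49 (limma adjusted p = 0.000516).

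Of 16 glycolysis genes 3 fell, and 5 fell when adjusted over the list alone: TDH2 (glyceraldehyde-3-phosphate dehydrogenase) by 0.55 ± 0.12, ADH1 (alcohol dehydrogenase) by 0.49 ± 0.12 and HXK2 (hexokinase) by 0.27 ± 0.08. The list mean differed by -0.15 (permutation adjusted p = 0.222) and by -0.20 within batches (0.0130). Of 42 respiration genes 2 fell, CIT1 (citrate synthase) by 0.51 ± 0.11 and LSC2 (succinyl-CoA ligase) by 0.46 ± 0.11, and 3 fell when adjusted over the list alone, with 0 rising. Of 18 sulfur and methionine genes 0 passed limma over all genes, and 1 rose and 5 fell when adjusted over the list alone; MET3 stood at -0.28 (limma adjusted p = 0.381) and at -0.45 with the batch as a term (0.0287).

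The other lists held few calls. When adjusted over the list alone, ribosome biogenesis genes had 0 calls, translation factors 1 rise of 26, proteasome genes 0 of 32, DNA damage genes 0 of 4 and phosphate genes 0 of 4. Ergosterol genes had 0 of 15, iron regulon genes 1 fall of 7 and nitrogen catabolite genes 0 of 3. Cell wall genes had 1 fall of 7 (CRH1, fell by 0.43 ± 0.12), a-cell genes 1 rise of 6 (MFA2, 0.49 ± 0.13) and haploid genes 1 fall of 6. Of the 4 alpha-cell genes, 0 had enough values to be tested. Further genes named by size were APT2 (0.59 ± 0.17, and 0.35 with the batch as a term, limma adjusted p = 0.0831), COA2 (0.41 ± 0.12), RRN3 (0.39 ± 0.11), a factor of RNA polymerase I, and NOP53 (0.29 ± 0.07), a ribosome assembly factor. On the low side were YCL021W-A (-0.58 ± 0.14), GTA1 (-0.53 ± 0.12), RPO21 (-0.53 ± 0.15), the largest subunit of RNA polymerase II, and GOR1 (-0.49 ± 0.13).

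By camera with its preset correlation, the large subunit ribosomal protein list was higher than other genes in small subunit deletions (adjusted p = 2.04e-17), and adjusted p = 0.0246 with an estimated correlation. Camera also put ribosome biogenesis genes (adjusted p = 1.52e-06; adjusted p = 0.541 with an estimated correlation), translation factors (0.00211; 0.149) and small subunit genes (0.00215; 0.689) higher. Stress-induced genes (4.18e-05; 0.689) and unfolded protein response genes (0.00034; 0.163) were lower by the same test. Over all 190 list and class pairs, camera called 52, of which 5 hold with an estimated correlation: large subunit ribosomal protein genes in small subunit deletions and in the contrast of both classes, sulfur genes in large subunit deletions, DNA damage genes in repair deletions and a-cell genes in sorting deletions. The number of genes called rested on single strains: 69 became 24 without RPS29A, 28 without RPS11A, 37 without RPS23A, 38 without RPS30B, 43 without RPS30A and 45 without RPS28B, and rose from 1.53% of the genes tested to 2.76%, 3.05%, 3.09% and 3.78% without RPS25A, RPS16A, RPS9B and RPS19B. Without the strains whose deleted gene was not lowered it was 2.87%.

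**Figure D2:**
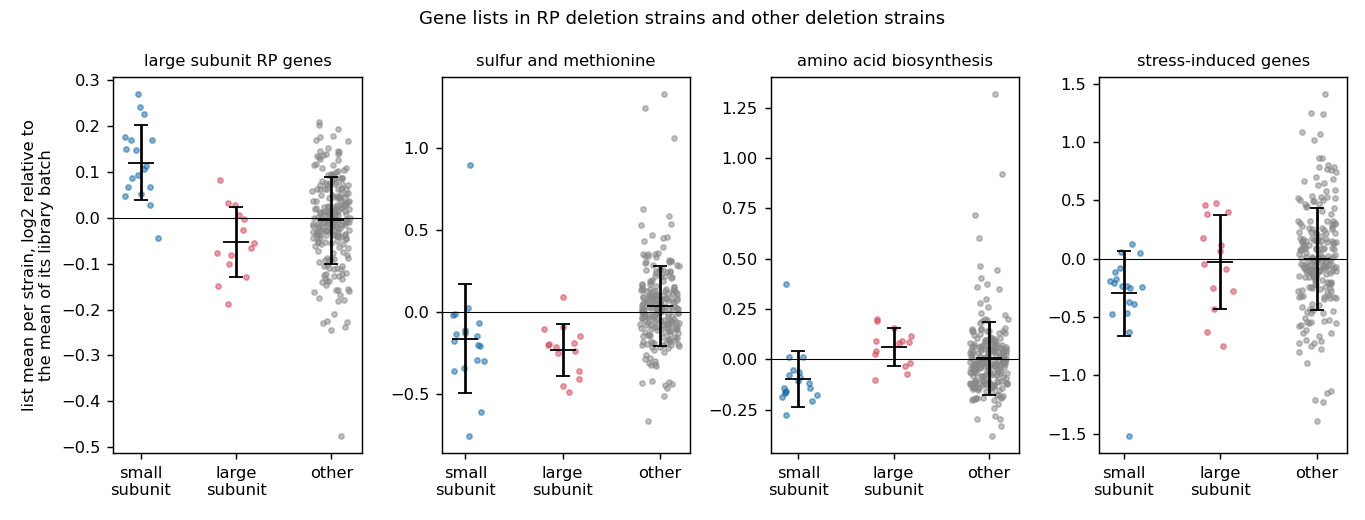
Points are strains without a small subunit protein (18), without a large subunit protein (14) and other deletions (all strains outside the classes), and the y axis is each strain's mean log2 ratio over a gene list relative to its library batch mean; bars are the mean ± SD of the group. The 4 panels show large subunit ribosomal protein, sulfur and methionine, amino acid biosynthesis and stress-induced genes; within batches small subunit deletions differ from other deletions by 0.13 in the first panel and by -0.32 in the last.

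Strains without a large subunit protein had higher mRNA of GCV1 and GCV3, subunits of the glycine cleavage system, lower TDH2 mRNA and a lower mean of the sulfur and methionine list. GCV1 (YDR019C, chromosome IV, 484163 to 485365), which encodes the T subunit of that mitochondrial enzyme, rose by 0.79 ± 0.15 (SE, n = 14 strains; limma adjusted p = 0.000179; higher in 13 of 14 strains), and GCV3, its H subunit, by 0.41 ± 0.10 (0.0259); GCV2, its P subunit, stood at 0.49 and did not pass (0.0865). TDH2 (YJR009C, chromosome X, 453683 to 454681) fell by 0.70 ± 0.13 (limma adjusted p = 0.000308; lower in 14 of 14). In total 10 genes passed limma, 3 higher and 7 lower, against 15 with the batch as a term, 6 higher and 9 lower, including all 10.

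The other named genes were VTC5 (0.59 ± 0.13), of the vacuolar polyphosphate complex, and, on the low side, the iron transporter FET4 (-0.61 ± 0.14), the ubiquitin-conjugating enzyme RAD6 (-0.58 ± 0.14), RPL7B (-0.58 ± 0.10), GND1 (-0.45 ± 0.10) of the pentose phosphate pathway and RPS14B (-0.40 ± 0.10). RPL8A, deleted in 1 strain of the class, stood at -0.64. The transcript of GCN4, the activator of amino acid biosynthesis genes, stood at 0.21 (limma adjusted p = 0.337) and at 0.27 ± 0.06 with the batch as a term (0.00327). Amino acid biosynthesis genes had 0 calls of 60 over all genes, and 2 rose when adjusted over the list alone; their list mean differed by 0.04 (permutation adjusted p = 0.707).

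All of the 18 sulfur and methionine genes had negative differences; 0 passed over all genes, and 8 fell when adjusted over the list alone. The list mean was 0.48 ± 0.20 (SD) against 0.74 ± 0.25, a difference of -0.26 (permutation adjusted p = 0.0247; 13 of 14 strains below the reference median). It was -0.25, -0.36, -0.17 and -0.34 in the 4 batches, the first with 1 strain of the class, and -0.27 over them (0.0105). With each strain centred on its median the difference was -0.27 and did not pass (adjusted p = 0.0865), nor did it without strains with a shifted chromosome (-0.25, 0.0632); with batch and centring together it was -0.29 and passed. Camera put the list lower (adjusted p = 1.27e-07; adjusted p = 0.0389 with an estimated correlation). Glycolysis genes had a mean difference of -0.18 (permutation adjusted p = 0.200) and -0.21 within batches (0.0205), and 3 of them fell when adjusted over the list alone. Large subunit ribosomal protein genes themselves had a mean difference of -0.07 (permutation adjusted p = 0.322), with 2 falls over all genes and 9 when adjusted over the list alone; their camera call (2.88e-05) was lost, adjusted p = 0.413 with an estimated correlation. That list holds the genes deleted in these strains, which lowers it by design. Without RPP2B the number of genes called was 4, without RPL37A it was 6, and without RPP1A, a strain with a raised chromosome IV, it was 17.

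Set directly against each other, both ribosomal classes differed in 10 genes, of which 4 encode small and 5 large subunit proteins; with only the strains of both classes in the fit 1 of the 10 remained. RPL7B (YPL198W, chromosome XVI, 173152 to 174702) was higher in small than in large subunit deletions by 0.75 ± 0.13 (SE, n = 18 and 14 strains; limma adjusted p = 2.88e-05), RPS24B by 0.47, RPL1A by 0.31 and RPL1B by 0.26. RPS22B was lower by 0.62 ± 0.12 (limma adjusted p = 0.00028), and so was MRPL49, of the mitochondrial ribosome (-0.50 ± 0.12). The remaining calls of the 10 were RPS9A (-1.06), RPL8A (0.66), RPS9B (-0.45) and RPL11B (0.28), which are deleted in a strain of either class or lie near such a gene.

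The mean of the 81 large subunit genes was 0.04 ± 0.12 (SD) in small and -0.13 ± 0.11 in large subunit deletions (difference 0.16, permutation adjusted p = 0.0241), and the difference was 0.27, 0.21, 0.11 and 0.25 in the 4 batches. This call ended with each strain centred on its median (0.24, adjusted p = 0.0865) and without strains with a shifted chromosome (0.14, 0.0863), and held with batch and centring together (0.24, 0.00095). Adjusted over the list alone, 17 of them were higher and 0 lower. The 81 include the genes deleted in large subunit strains, which lowers that class for these genes by design. The call for the list mean nevertheless held when genes deleted in any strain were left out, a setting fixed beforehand. Amino acid biosynthesis genes had a difference of -0.16 that did not pass (permutation adjusted p = 0.102) but did within batches (-0.16, adjusted p = 0.0298; -0.28, -0.15, -0.09 and -0.28). With the batch as a term 49 genes passed limma, 20 higher and 29 lower, among them 6 genes of the small and 15 of the large subunit. Of the 49, 7 are deleted in a strain of either class or lie near such a gene: RPS9B, RPS9A, RPL9A, RPL11B, RPL8A, RPL6B and RPL21B. RPL29, also called, is deleted in a large subunit strain, so part of these differences is built in. With each strain centred as well 34 were higher and 12 lower. The 49 included TIF4631, encoding the scaffold of the cap-binding complex (0.64; pooled 0.66 with limma adjusted p = 0.0515), HSP78 (-0.60), HSP104 (-0.52) and PCL5 (-0.70), a cyclin for Gcn4 turnover. Without RPS11A, RPS1B or RPS29A the 10 calls became 5, without RPL19A, RPS28B or RPS30B 6, without RPL29 or RPS16A 16, and without RPS19B 18.

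As labelled, strains lacking a vacuolar or endosomal sorting factor had lower mean mRNA of genes that a cells use for mating. The fall was carried mainly by the libraries labelled VPS53, VPS24, VPS51 and PEP8. MFA1 (YDR461W, chromosome IV, 1385176 to 1385286), which encodes the a-factor pheromone, fell by 0.89 ± 0.17 (SE, n = 13 strains; limma adjusted p = 0.00114; lower in 12 of 13). STE2, the receptor for alpha factor, fell by 0.58 ± 0.11 (0.000556; 12 of 13), MFA2, another a-factor gene, by 0.69 ± 0.16 (0.0204) and KAR4, a pheromone response regulator, by 0.67 ± 0.16 (0.0426). The fifth call, QDR2 (-0.43 ± 0.11), lies outside the rule for named genes and was chosen after its values were seen. The a-cell list mean was -0.69 ± 0.78 (SD) against -0.07 ± 0.32 (difference -0.62, permutation adjusted p = 0.0038; lower in 11 of 13 strains), and 6 of 6 members fell when adjusted over the list alone. By strain the list mean was -2.49 in VPS53, of the GARP complex, and -1.57, -1.39 and -1.30 in the libraries labelled VPS24, VPS51 and PEP8, and it lay between -0.61 and 0.15 in the other 9. The libraries labelled VPS24 and VPS51 did not have their gene lowered. The library labelled PEP8 had RPP1A at -3.41 relative to the batch median, as low as the RPP1A library itself (-3.34), correlated with that library at 0.92, and shared its a-cell list mean (-1.32 in RPP1A). Without the strains with a shifted chromosome, PEP8 among them, the a-cell difference was -0.57 (permutation adjusted p = 0.0038), with each strain centred -0.64 (0.0019), and without those whose gene was not lowered -0.51 (0.0119). No setting left out VPS24, VPS51 and PEP8 together. Haploid and pheromone genes were also low in these libraries, at -1.67 in VPS53 and at -0.62, -1.15 and -0.63 in those labelled VPS24, VPS51 and PEP8, and relative to the batch mean VPS53 and VPS51 were the lowest of all strains; the class differed by -0.27 (permutation adjusted p = 0.206), and by -0.39 within batches (0.0130). Whether the cell type of these cultures had changed was not tested. Within batches the a-cell difference was -0.91 and -0.70 in the first and last, and 0.10 and 0.08 in the others, which hold 1 and 2 strains of the class. The 5 calls became 1 without VPS53, 2 without PEP8 or VPS24, and 3 without VPS8, VPS9, VPS27 or VPS30, and 0 without the 3 strains whose deleted gene was not lowered.

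Strains lacking a recombination repair gene had higher mRNA of RNR4, a subunit of ribonucleotide reductase, the enzyme that makes deoxyribonucleotides. RNR4 (YGR180C, chromosome VII, 855264 to 856301) rose by 0.63 ± 0.11 (SE, n = 8 strains; limma adjusted p = 7.91e-05; higher in 8 of 8), and was the 1 gene called. RNR2 stood at 0.64 (limma adjusted p = 0.191) and at 0.65 ± 0.14 with the batch as a term (0.0114). The mean of the 4 DNA damage genes tested was 0.35 ± 0.43 (SD) against -0.16 ± 0.34 (difference 0.51, permutation adjusted p = 0.0152; higher in 7 of 8 strains), and 0.39 and 0.44 in the 2 batches that hold the class. With each strain centred on its median that difference was 0.44 and no longer passed (adjusted p = 0.0865), though it did with batch and centring together (0.42). It was 1.00 in RAD52, 0.68 in RAD57 and 0.52 in RAD55, and -0.12 in the library labelled MRE11, whose deleted gene was not lowered. Without RAD57 there were 2 calls.

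Among ribosome biogenesis factor deletions, a transcript at YGL088W rose by 2.68 ± 0.28 (SE, n = 7 strains; limma adjusted p = 2.32e-15). This open reading frame (chromosome VII, 345836 to 346201) overlaps the small nucleolar RNA gene SNR10 (345986 to 346230) on the same strand. It stood at 7.83 in LRP1 and 7.42 in RRP6, which encode a cofactor and a nuclease of the nuclear exosome, and at 5.03 in the library labelled TMA23, against -0.09 to 1.36 in the other 4 libraries. The SE and p-value for YGL088W use the spread over all groups, so they understate this spread within the class. The library labelled TMA23 did not have its own gene lowered (0.11 relative to the batch median). YHR095W, which has no match in the annotation used here, rose by 1.57 ± 0.31 (limma adjusted p = 0.00114), with 6.42 in RRP6 and 4.82 in LRP1. The 2 calls became 1 without LRP1 or without RRP6 and 3 without TSR2.

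Mediator deletions had higher CTT1 (YGR088W), the cytosolic catalase, by 1.75 ± 0.34 (SE, n = 4 of the 6 strains with a value; limma adjusted p = 0.0019), with 3.79 in SSN2, 3.75 in CSE2, 1.92 in SIN4 and 1.27 in SRB8; relative to the batch mean these were 2.57, 2.53, 1.28 and 0.14. MNN4, a regulator of mannan phosphorylation, rose by 1.52 ± 0.30 (limma adjusted p = 0.0019; higher in 6 of 6, and above the batch mean in 5) and by 0.88 ± 0.19 with the batch as a term. SHM2, the cytosolic serine hydroxymethyltransferase, fell by 0.75 ± 0.17 (limma adjusted p = 0.0114; lower in 6 of 6, and below the batch mean in 4). The exceptions were the libraries labelled SOH1 and SRB2, whose deleted gene was not lowered. These were the 3 calls, and without CSE2 or without SSN2 there were 0. SHM2 was lowest in SRB8, a library with a raised chromosome XI, at -1.96 relative to the batch mean. Without SRB8 there were 2 calls, both higher, so SHM2 no longer passed. Without strains with a shifted chromosome CTT1 and MNN4 held and SHM2 did not.

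Elongator and URM1, chromatin and mitochondrial deletions gave 0 genes by limma, with 3.91%, 5.27% and 2.49% of the genes tested at an unadjusted p under 0.05. With the batch as a term, Elongator and URM1 deletions had higher RPS14B (0.56 ± 0.10; limma adjusted p = 0.000797; n = 6, above the batch mean in 5) and lower KTR1 (-0.56 ± 0.13; 0.0348; below the batch mean in 6 of 6), and the other classes again had 0, with 337 and 230 genes at an unadjusted p under 0.05. The list mean of respiration genes differed by -0.14 in mitochondrial deletions (n = 12), which did not pass (permutation adjusted p = 0.200), and by -0.15 within batches (0.0499). Their camera call (2.13e-09) was lost, adjusted p = 0.0600 with an estimated correlation.

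Across all strains, ribosomal protein mRNA ran against stress mRNA, and ribosome biogenesis mRNA ran with amino acid biosynthesis mRNA. The family held 28 pairs of list means, each tested by two-sided permutation with adjustment over the family. With batch means subtracted, ribosomal protein and stress-induced genes had r = -0.62 and rho = -0.61 (n = 328; permutation p = 1e-05 for each, the smallest these permutations can give; adjusted p = 2.33e-05), and r = -0.76, -0.60, -0.62 and -0.48 within the batches. Pooled r was -0.63 (rho -0.60), and -0.62 without the 2 strains farthest from the median. Ribosome biogenesis genes also ran against stress-induced genes, with r = -0.57 and rho = -0.54 (permutation p = 1e-05; adjusted p = 2.33e-05) and -0.65, -0.43, -0.46 and -0.66 within batches; without the 2 farthest strains r was -0.55. Stress-induced and respiration genes rose and fell together (r = 0.67, rho = 0.65, permutation p = 1e-05, adjusted p = 2.33e-05), with 0.74, 0.36, 0.62 and 0.71 within batches and 0.65 without the 2 farthest strains.

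The lists named in the series title were less tightly tied. Ribosome biogenesis and amino acid biosynthesis genes had r = 0.22 and rho = 0.27 with batch means subtracted (permutation p = 0.00016 and 1e-05; adjusted p = 0.000264 and 2.15e-05), within batches 0.23, 0.18, 0.24 and 0.21, and 0.22 without the 2 farthest strains; pooled r was 0.35 (rho 0.44). Ribosomal protein and amino acid biosynthesis genes had r = -0.16 and rho = -0.21 (permutation p = 0.00497 and 0.00028; adjusted p = 0.00696 and 0.000461), within batches -0.12, -0.38, -0.19 and -0.11, -0.19 without the 2 farthest strains and pooled r = -0.23 (rho -0.25), and this sign turned to 0.18 when each strain was centred on its median. Ribosomal protein and ribosome biogenesis genes had a pooled r of -0.03 (rho 0.01, permutation p = 0.578 and 0.881), and r = 0.27 (rho 0.27, permutation p = 1e-05 for each, adjusted p = 2.33e-05) with batch means subtracted. That relation was 0.41, 0.14, 0.36 and 0.15 within batches and 0.25 without the 2 farthest strains. Of the 28 pairs, 25 passed pooled, 24 with batch means subtracted, and 13 had the same sign in all 4 batches.

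Strains that lack a known regulator were paired beforehand with the list it acts on, and 1 library per strain allows a rank but no test. Proteasome genes were lowest of all 328 strains in the strain without RPN4, their activator, at -1.11 against -0.10 ± 0.20 (SD) elsewhere; 32 of 32 members lay below the batch mean, PRE1 at -1.37, PRE2 at -0.94 and PRE3 at -0.69. Phosphate genes were highest in the strain without PHO80, the cyclin that holds them off, at 1.82 (VTC1 2.42, VTC3 2.89, VTC4 1.71). Ergosterol genes were highest in the strain without ERG2, a sterol isomerase, at 0.31 (ERG3 1.499, ERG1 0.35, and ERG2 itself -3.70). Respiration genes were highest in the strain without HXK2, a hexokinase needed for glucose repression, at 0.85 (CIT1 1.24, ACO1 0.88, IDH1 -0.27); relative to the batch mean, which 42 of 42 members exceeded, it was at rank 2 with 0.69. Cell wall genes were at rank 3 from the highest in the strain without FKS1, the glucan synthase, at 1.42 (CRH1 1.19, GSC2 2.02, SLT2 1.47).

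Most other pairs stood closer to the middle of the 328 strains. Stress genes in the strain without RAS2, an activator of protein kinase A, were at -0.43, rank 11 from the lowest, and in TPS1 at 0.68, rank 69 from the highest. Glycolysis genes in GCR2, their activator, were at -0.46, rank 33 from the lowest, and iron genes in the library labelled FTR1 at -2.05, rank 10 from the lowest. Sulfur genes were at 0.46 in CBF1 and 0.74 in MET10. In HMO1, small and large subunit ribosomal protein genes were both at -0.20, with RPS0A at -1.37. Ribosome biogenesis genes in TOD6 were at -0.22, and cell wall genes in the library labelled GAS1 at 0.10. The library labelled URE2, whose own gene stood at -0.36, had the lowest nitrogen catabolite genes as given, at -1.04, and rank 2 from the lowest relative to the batch mean, at -0.96 (GAP1 -1.02, DUR12 -1.02, DAL2 -1.08). By contrast, the library labelled RPS10B had the lowest URE2 (-1.83 relative to the batch median) and the highest nitrogen catabolite genes (3.17 relative to the batch mean). The pairs were fixed without a direction, so a low or high list mean does not show how the deleted gene acts.

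**Figure D3:**
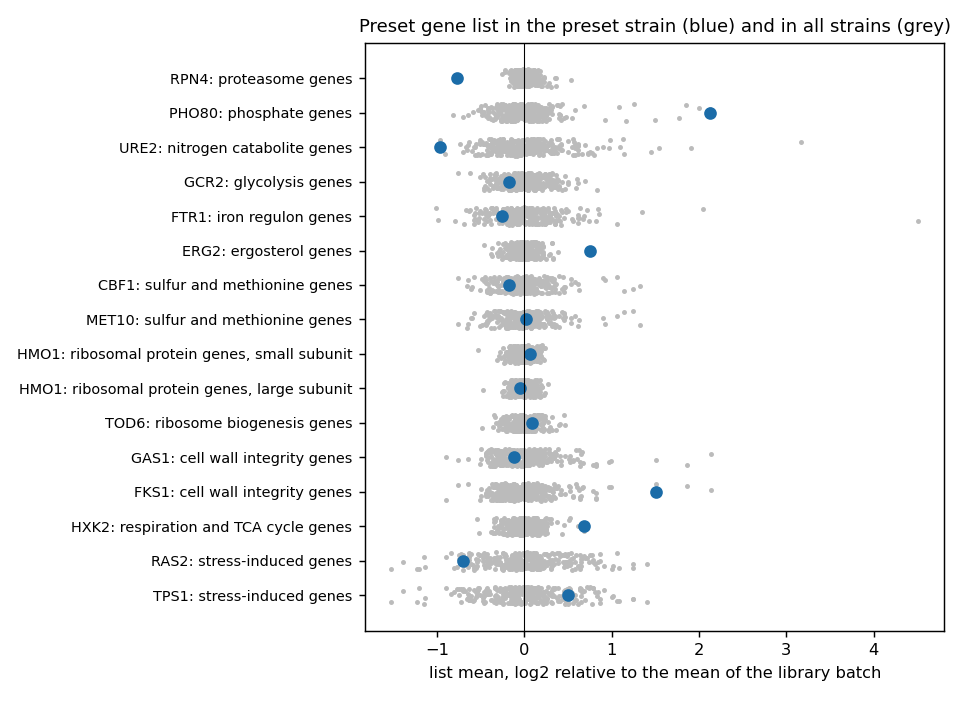
Each line shows 1 pair of a deleted regulator or pathway gene and its gene list; the x axis is the list mean in log2 relative to the library batch mean, with all strains in grey and the paired strain in blue. The strain without RPN4 sits at -0.77, the strain without PHO80 at 2.13 and the strain without ERG2 at 0.75.

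In 16 libraries the genes of a whole chromosome were raised by over 0.4 relative to the strain's other genes, where 1 extra copy in a haploid cell would give 1. The shifts ranged from 0.52 (CTF18, chromosome IX) to 0.95 (SRB8, chromosome XI), against an SD of 0.0481 for the other chromosome shifts. Chromosome IX was raised in LRP1 (0.94), RPS24A (0.73), UBP3 (0.68) and CTF18, chromosome IV in RPP1A (0.87) and in the library labelled PEP8 (0.87), whose profile resembled RPP1A, and chromosome XI in SRB8 and RPS27B (0.86). One strain had a lowered chromosome, I, at -0.45. Without these 17 strains the number of genes called for small subunit deletions was 45.

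**Figure D4:**
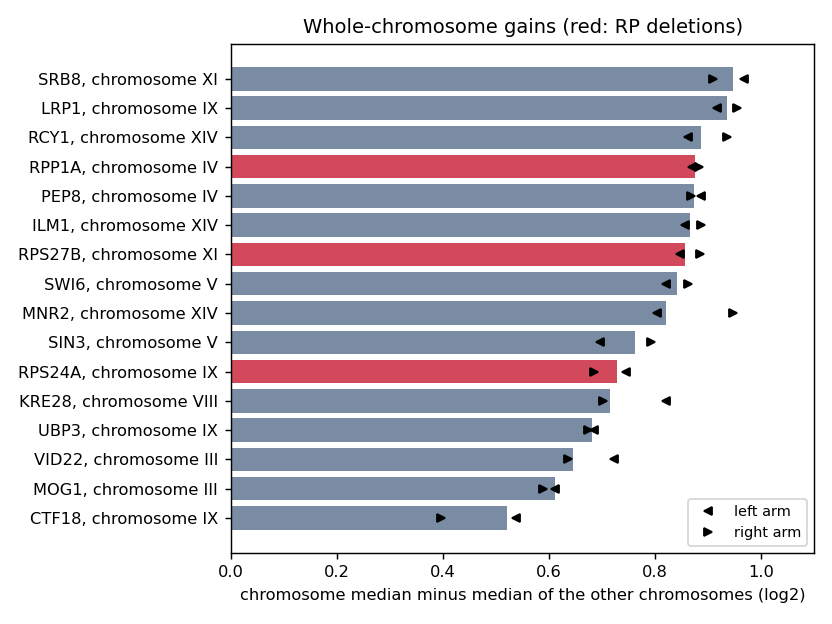
Bars give, for the 16 strains with a raised chromosome, the median log2 ratio of that chromosome's genes minus that of the strain's other genes, with ribosomal protein deletions in red; triangles give the same for the left and right arm. The bars run from 0.52 to 0.95.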

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

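The tests of library batch, chromosome gains and median offset and the regroupings of strains in this part were chosen only after the results were seen; the comparison of small with large subunit deletions was planned.

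The mean of the large subunit ribosomal protein genes differed between both ribosomal classes, by 0.16 (permutation adjusted p = 0.0241; 0.24 and 0.0865 with centring), and small subunit deletions also had higher values than the other deletions once library batches were accounted for. The tables argue against 3 possible sources of the higher values. Within batches the difference from other deletions was 0.13 against 0.09 pooled, so differences between the batches found in the values did not create it. A technical batch that these groups miss is not excluded. Without strains with a chromosome shift it was 0.12, and with each strain centred on its median 0.18, so neither raised chromosomes nor an offset of whole libraries accounts for it. Reads shared between near-identical gene copies were not tested for this pattern and stay open beside an effect of the missing subunit, which the design names.

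Ergosterol genes had a mean of -0.79 in the library labelled SRB8, far from the nearest of the other 5 Mediator libraries at -0.38; among 76 such group and list tests this was the 1 found, where chance gives about 3.8. These tests did not account for the batch. SRB8 is the only Mediator library of its batch, and relative to the batch mean its ergosterol genes stood at -0.37.

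Chance is argued against, before any adjustment over the contrasts, for the count of small subunit deletions. The strains were regrouped at random into sets of equal size, 100 regroupings each with the real one included and without adjustment over the contrasts. As many genes as the real 69 came up in 1 regrouping for small subunit deletions, the real one (highest other 39). As many as 10 came up in 2 for small against large subunit (highest other 15), which does not decide over this many contrasts. With 100 regroupings no contrast could pass an adjustment over all of them. Chance stays possible for the other classes with genes called. For large subunit deletions 4 regroupings gave as many as 10, and the highest other gave 62. For sorting deletions 3 regroupings gave as many as 5 (highest other 25) but 5 did within batches and with the batch as a term (highest other 55). Further, 13 gave as many as the 3 genes of Mediator (highest other 277), 16 as many as the 1 of recombination repair (highest other 239) and 14 as many as the 2 of ribosome biogenesis factors (highest other 18). For Elongator and URM1, chromatin and mitochondrial deletions, with 0 genes by limma and 3.91%, 5.27% and 2.49% of the genes tested at an unadjusted p under 0.05, the regroupings decide nothing, since all 100 must reach a count of 0; the highest others were 2.27%, 1.89% and 0.289% of the genes tested. The regroupings within batches, with the batch as a term, shuffled the labels of all classes over all strains. There the 3.45% of genes for small subunit deletions stood against a highest other of 0.267%. Of these regroupings 4 gave as many as the 15 genes of large subunit deletions (highest other 80). As many as the 49 of small against large subunit came up in 1 (highest other 16). For that contrast the shuffled sets hold strains of any class, so whether both ribosomal classes can be exchanged was not tested there.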

How the results depend on the processing

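All alternatives that use library batches, the deleted gene's own level, the first table alone or a strain left out were chosen after seeing the data; the rest were planned. Counts are of genes called, in the order the classes are named, but for small subunit deletions they are a percent of the genes tested in that fit, 1.53% as reported; the cause was not tested except where fewer strains or genes were used. Large subunit deletions stayed within 1.5 times of 10 genes under centring, complete genes, another reference and all batch terms with every strain, and chromatin and mitochondrial deletions stayed at 0 by limma under every setting run, with 5.27% and 2.49% of genes at an unadjusted p under 0.05. Moderated variances with a trend changed no count by over 1.5 times. Depth is unknown, so what it limits could not be assessed.

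With each strain centred on its median, 0.911% of genes were called for small subunit, and 5 genes for Mediator and 3 for sorting deletions. With only genes complete in all strains (fewer genes) there were 4.62% for small subunit, 7 for recombination repair, 0 for ribosome biogenesis factors (limma; 3.85% at an unadjusted p under 0.05 over all genes) and 18 for small against large subunit. With all strains outside the class as reference sorting deletions had 3, and with only both classes in the fit small against large subunit had 1. With the batch as a term, small subunit, Elongator, Mediator, recombination repair, ribosome biogenesis and small against large subunit had 3.45%, 2, 7, 2, 5 and 49; with 5 batches 2.78%, 2, 7, 2, 7 and 25; with batch and centring 2.69%, 1, 7, 2, 6 and 46. The first table alone (fewer strains) gave 3.80% for small subunit, 0 for Mediator (limma; 409 at an unadjusted p under 0.05 with both tables), 1 for ribosome biogenesis and 6 for small against large subunit.

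Without strains with a chromosome shift there were 1.0% for small subunit, 16 for large subunit, 2 for recombination repair, 2 for sorting and 6 for small against large subunit; with the batch as a term as well, 0.934%, 28, 2 and 3 for the first 4, 31 for the contrast, 2 for Elongator and 1 for Mediator. Without strains whose deleted gene was not lowered there were 2.87% for small subunit, 6 for Mediator, 3 for recombination repair and 0 for sorting (limma; 280 at an unadjusted p under 0.05 with them). With the batch as a term as well, there were 5.20% for small subunit, 23 for large subunit, 1 for Elongator, 13 for Mediator, 2 for recombination repair, 4 for ribosome biogenesis, 1 for sorting and 29 for small against large subunit.

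Leaving out 1 strain at a time gave 0.533% (RPS29A) to 3.78% (RPS19B) for small subunit, also 0.622%, 0.822%, 0.845%, 0.956% and 1.0% without RPS11A, RPS23A, RPS30B, RPS30A and RPS28B, and 2.76%, 3.05% and 3.09% without RPS25A, RPS16A and RPS9B. It gave 4 (RPP2B) to 17 (RPP1A) for large subunit, with 6 without RPL37A; 0 (CSE2 or SSN2) to 4 for Mediator; 1 (VPS53) to 7 (TLG2) for sorting; 1 to 2 (RAD57) for recombination repair; 1 (LRP1 or RRP6) to 3 (TSR2) for ribosome biogenesis; and 0 to 2 for Elongator, with 1 without KTI12 and 2 without ELP6. For small against large subunit it gave 5 (RPS11A, RPS1B or RPS29A) to 18 (RPS19B).

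The 5 list means past the threshold became 1 with centring (a-cell genes in sorting deletions), 3 without chromosome-shift strains, 16 within batches, 18 within batches with centring, 9 within batches without chromosome-shift strains, 11 without strains whose gene was not lowered and 15 with that and batches, and 9 for the first table alone. The 52 camera calls became 5 with an estimated correlation and 6 with that and the batch. The deleted gene was under -1 in 63.2% of strains where it kept a value, against 33.5% where it was lowest. Relative to the batch, RPN4 stood at -0.77, GCR2 at -0.18, FTR1 at -0.26, ERG2 at 0.75, CBF1 at -0.18, MET10 at 0.0201, HMO1 at 0.0628 for small and -0.0437 for large subunit genes, and TOD6 at 0.0900.

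Correlations that changed sign and passed the threshold pooled or in the setting named were, with centring, ribosomal protein (RP) with ribosome biogenesis (0.2565), amino acid (0.1837), respiration (0.4115) and glycolysis (0.3626) genes, biogenesis with translation factors (0.1839), amino acid genes with translation factors (0.2558), glycolysis (0.1994) and proteasome (-0.1428), and stress with proteasome (-0.1905). With batch means subtracted they were RP with biogenesis (0.2667), translation factors with biogenesis (0.349), amino acid (0.137) and respiration (-0.1558) genes, and respiration with proteasome (0.1557); without chromosome-shift strains as well these were 0.288, 0.3473, 0.1374, -0.1433 and 0.1444. With batch and centring they were RP with biogenesis (0.4887), amino acid (0.1141) and proteasome (0.09736) genes, translation factors with biogenesis (0.4748), amino acid (0.2365) and proteasome (0.03416) genes, and proteasome with amino acid (-0.06321), stress (-0.1123) and respiration (0.027) genes. Of the other results, 326 kept their side of the threshold, 42 passed it and 20 no longer did. Those that kept their side could still turn sign without passing. Amino acid with glycolysis genes did so with batch means subtracted, from -0.0935 to 0.0726. No alternative pseudocount and no filter on level could be run, since no levels are given.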

Other observations

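The test of whether doubtful libraries resemble the strain of another lowered gene was planned before its result was seen; the Fisher tests, the paralog test, the arm test and the profiles without shifted chromosomes were chosen only after. Single strains stood far from their library batch in single lists, and these were chosen after their values were seen. Iron regulon genes were at 4.51 relative to the batch (10.9 SD; 3.39 as given) in the strain without GSH1, which makes glutathione, at 2.04 without FLX1, a mitochondrial carrier, and at 1.34 without FRA1, which restrains the iron regulator. Amino acid biosynthesis genes were at 1.32 (7.56 SD; 0.89 as given) without DAL81, a regulator of nitrogen use, and at 0.92 without DEG1, a pseudouridine synthase of transfer RNA. Unfolded protein response and cell wall genes were at 1.71 and 2.14 without ARV1, which acts in lipid transport; the former were at 1.12 without CSF1 and 1.09 without PSD1. DNA damage genes were at 1.42 without RAD27, the flap nuclease, and 1.17 without RAD52.

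Stress-induced genes were highest without VIP1 (1.41), CHO2 (1.25) and SLA1 (1.24) and lowest without RPS27B (-1.52). Translation factor genes were lowest without the histone chaperone ASF1 (-0.58, -7.12 SD). In the library labelled THP1, whose own gene was not lowered, ribosomal protein genes of the small subunit were at -0.52 and of the large subunit at -0.48. Phosphate genes were at 1.997 in the library labelled VPS24, whose own gene was not lowered, and at 1.86 without MSN5, a nuclear exporter. The remaining copy of the 31 ribosomal protein genes with a measured copy lay 0.39 ± 0.66 (SD) above the batch mean, higher in 26 of 31 strains (sign-flip permutation p = 1e-05, the smallest these can give), and 0.34 ± 0.68 in the 27 strains with no chromosome raised by over 0.3; RPS9A without RPS9B (3.29) and RPL9B without RPL9A (1.53) were highest.

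The raised chromosomes among ribosomal protein deletions carried the other copy of the deleted gene in 3 of 3 strains: RPP1B on chromosome IV without RPP1A, RPS24B on IX without RPS24A and RPS27A on XI without RPS27B. Permuting the copies' chromosomes among the 31 strains with a copy gave this with an exact p of 0.000371, which is consistent with the hypothesis that cells with an extra copy of the chromosome that carries the remaining gene were selected. A change in part of the chromosome is argued against, since the smaller arm shift was at least 0.918 of the larger one. In 2 of the 3, RPS24A and RPS27B, that chromosome is not the deleted gene's own. Whether the raised chromosomes arose in these cultures or in the strain collection stays open.

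Of 258 libraries checked, 60 did not have their labelled gene lowered; reads shared with a copy of the gene are argued against as the general cause, since 18.75% of ribosomal protein deletions, most of which have a copy, were not lowered against 23.89% of the others (one-sided Fisher's exact p = 0.805). Another studied gene was lowest of all libraries by over 5 median absolute deviations in 20% of these libraries against 11.6% of the rest, which does not decide (Fisher's exact p = 0.130). In 3 of 12 such libraries the closest profile was the library labelled with that other gene, and in 2 of them, MON1 (closest to GNP1) and RPS16A (MSN5), also without the genes of shifted chromosomes (binomial p = 0.000605), so a wrong or mixed strain may be their source, whereas the match of UBP3 with CTF18 (r = 0.20) fell to 0.0799 without chromosome IX, raised in both. Among libraries counted as lowered, PEP8 (-0.58) had RPP1A at -3.41 and matched the RPP1A library at r = 0.81 without chromosome IV, and MNR2 (-0.53) had the lowest ILM1 (-1.60) and matched that library at 0.52 without chromosome XIV, which a wrong or mixed strain could give. The library labelled RPS10B had the lowest URE2 (-1.83) and nitrogen catabolite genes at 3.17, and the library labelled YAF9 had the lowest VPS24 (-2.94), which a wrong or mixed strain could also give but no profile test decided.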
